A study of Mus musculus with 26 samples.

How the data were processed

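RNA of the mouse left ventricle was measured in 26 libraries of 4 groups, taken from the sample titles: wild type (wt, 6), Mst-1 overexpression (MstTg, 7), galectin-3 knockout (Gal3Ko, 8) and both (Mst1Gal3, 5). Per the labels, RNA was extracted with Trizol and Direct-zol columns and 200 ng of total RNA was depleted of ribosomal RNA before a directional NEBNext library. The submitters' processing notes name bcl2fastq 2.19.1.403, STAR, featureCounts and the build GRCm38. The versions of STAR and featureCounts, the annotation release, the strand setting and the treatment of multi-mapping reads are not given in the sources used here. Raw reads were not analysed here.

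The deposited table holds raw read counts per gene, whole numbers with no normalization, for 15249 genes and 26 libraries. All 26 columns matched a sample of the labels. The lowest mean count of any gene over the libraries was 10.0, so genes below that level were absent from the deposited table and could not be tested. Of the gene identifiers 15195 were found in GENCODE M21 and 54 were not, and 14740 had the same symbol there. Positions were taken from that annotation. Library totals were 18580405 to 32663735 counts, and 1 count at the lowest total equals 0.0538 CPM. Intervals and floors (3 counts) cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Pairs of replicates were checked for duplicates, and the lowest chi-square per degree of freedom of any pair was 4.90.

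Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on counts: TMM factors, filterByExpr (which removed 0 genes), estimateDisp, robust glmQLFit and glmQLFTest, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All 26 libraries were in 1 fit with a mean per group, which left 22 residual degrees of freedom and a common biological coefficient of variation of 0.114. The comparisons were MstTg against wt, Gal3Ko against wt, Mst1Gal3 against MstTg, Mst1Gal3 against Gal3Ko and the interaction, (Mst1Gal3 minus MstTg) minus (Gal3Ko minus wt), which is also the Mst-1 response in the galectin-3 knockout minus that outside it. CPM are edgeR's scaled counts on TMM-adjusted library sizes, and log2 CPM per library used a prior count of 0.5.

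Gene lists were written before the data were examined, as were the comparisons, the tests, the rule for named genes and the alternatives named as chosen beforehand below. Lists were tested with camera of limma 3.58.1 on voom values, two-sided, with the preset correlation of 0.01 between genes, and adjusted over 31 lists with at least 3 measured members. Stk4 and Lgals3 were left out of lists. Calls are given beside those of camera with an estimated correlation. Lists were also tested with fry, which tests whether the genes of a list move 1 way and does not compare them with other genes. Its calls are given as counts, and for some lists that camera did not call. Lists overlap in part, for example Ctgf and Tgfb2 are in both the fibrosis and the YAP/TEAD lists. The lymphocyte list (2 of 16 genes measured) and the adipocyte list (2 of 8) were too short to test. Incomplete lists were neutrophil markers (3 of 12), mitochondrial-encoded respiratory chain (7 of 13), galectins (6 of 8), inflammatory mediators (19 of 23), integrated stress response (19 of 21), atrial (8 of 10), mesothelial (5 of 7), Schwann cell (5 of 6), YAP/TEAD (23 of 24), p53 (18 of 19) and cell cycle (21 of 22).

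Genes were named by rule: Stk4 and Lgals3 in every library first, then fixed readout genes, the 8 largest changes up and the 8 down per comparison among called genes with a mean of at least 1 CPM and a symbol that is not a gene model name, and up to 4 members with the smallest p of each list described. Genes named outside this rule are said to be so. Library measures (total count, mitochondrial share, mitochondrial ribosomal RNA share, share of the 10 highest genes and genes detected) were compared with exact permutation tests of the difference of means, two-sided, adjusted over 20 tests. The mitochondrial ribosomal RNA share was added after the table was seen.

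Shares of called genes within 20 Mb of Lgals3 were tested with Fisher's exact test, two-sided, against all tested genes with a known position, targets left out, with exact (Clopper-Pearson) 95% intervals. The window was written before the positions of the calls were seen.

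The pipeline was tested on simulated data made from the wt means, the library totals and the common dispersion of the table, with 50 genes changed at each of 4 sizes per comparison. At a 1.5-fold change it recovered 72% for MstTg against wt, 86% for Gal3Ko against wt, 84% for Mst1Gal3 against MstTg, 78% for Mst1Gal3 against Gal3Ko and 50% for the interaction. At a 1.25-fold change it recovered 38, 26, 24, 30 and 2%. Of 15019 genes simulated without change, some of which the filter removed (14997 to 15037 genes were tested, changed ones included), 9, 11, 7, 8 and 8 were called.

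Alternatives chosen beforehand were median-of-ratios (RLE) size factors, a stricter filter at a mean of 1 CPM, no filter, DESeq2 1.42.0, limma-voom, limma-voom with quality weights, fits of the compared groups alone, the replicate number as a block, mitochondrial-encoded genes left out, each library left out in turn, a threshold of 0.01 and a fold of at least 1.5. Those chosen after seeing the data were library totals without TMM factors, chromosome 14 left out, the 6 libraries with raised atrial genes left out and the mean log2 CPM of kidney genes as a covariate. The atrial limit of 30 CPM for the sum of Myl7, Myl4, Sln and Mybphl was picked after the sums were seen, and 100 was also considered. A covariate of Xist was chosen beforehand but not run, because Xist is not in the table. The labels give no batch, age, litter or date, so none was modelled.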

Results

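Left ventricle RNA was sequenced from mice in 26 libraries that cross 2 genotypes. The first is overexpression of the Hippo pathway kinase Mst-1 (gene Stk4). The other is knockout of galectin-3 (gene Lgals3), a secreted carbohydrate-binding protein made by macrophages and injured tissue. There were 6 libraries from wild-type controls (wt), 7 with Mst-1 overexpression alone (MstTg), 8 with the galectin-3 knockout alone (Gal3Ko) and 5 with both (Mst1Gal3). The design text presents the Mst-1 mouse as a model of dilated cardiomyopathy, and the comparisons ask what Mst-1 does to the ventricle and whether loss of galectin-3 alters that. Library totals ran from 18580405 to 32663735 counts, so 1 count in the smallest library was 0.0538 CPM (the count scaled by library size, as edgeR computes it). Totals did not differ between groups in any of the 4 exact permutation tests (two-sided, lowest p = 0.414, Benjamini-Hochberg adjusted p = 0.592). Transcripts of the mitochondrial genome took 31% ± 2.36 (SD) of counts in wt and 33.0% ± 3.64 in Gal3Ko, against 17.7% ± 2.79 in MstTg and 18.7% ± 2.95 in Mst1Gal3. That share differed between MstTg and wt by an exact permutation test (p = 0.00117, adjusted p = 0.00389 over 20 tests of library measures). It also differed between Mst1Gal3 and Gal3Ko (exact permutation p = 0.00155, adjusted p = 0.00389). The mitochondrial ribosomal RNA share, the share of the 10 highest genes and the number of genes detected differed in both comparisons too (exact permutation tests, each adjusted p = 0.00389). Between Mst1Gal3 and MstTg only the number of genes detected differed (15246.4 against 15241.4, exact permutation p = 0.00758, adjusted p = 0.0168). The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were counted in all 26 libraries. The labels do not state that the replicates of a group are separate animals, so the p-values measure the spread between these samples. Changes below are log2 fold changes ± SE with adjusted p-values of edgeR for genes and of camera for gene lists, unless another tool is named.

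Stk4, the overexpressed gene (ENSMUSG00000018209, GRCm38 chromosome 2, 164070322 to 164155524), had 454 to 692 counts in the wt libraries and 388 to 718 in Gal3Ko, against 22011 to 31877 in MstTg and 19919 to 28364 in Mst1Gal3. Its level was 23.6 CPM ± 1.27 (SD, n = 6) in wt and 949 CPM ± 74.7 (n = 7) in MstTg, a 40.1-fold difference. Lgals3 (ENSMUSG00000050335, chromosome 14, 47367751 to 47386160) was scarce in the control ventricle, with 19 to 49 counts per library, and rose with Mst-1 to 1126 to 1791 counts. It stood at 1.64 CPM ± 0.495 (SD, n = 6) in wt, 55.2 CPM ± 3.39 (n = 7) in MstTg, 2.14 CPM ± 0.369 (n = 8) in Gal3Ko and 3.91 CPM ± 1.04 (n = 5) in Mst1Gal3. In the Mst-1 background the knockout lowered Lgals3 14-fold (log2 fold change -3.81 ± 0.13 SE, adjusted p = 8.13e-19). In Gal3Ko Lgals3 was not lower than in wt: it had 22 to 64 counts per library, and the estimate was above 0 (0.41 ± 0.17, adjusted p = 0.619). The knockout therefore did not show as a fall of Lgals3 counts outside the Mst-1 background, and galectin-3 loss names the genotype of the labels, since the protein was not measured. Lgals3 was higher in Mst1Gal3 than in Gal3Ko (0.86, adjusted p = 1.18e-05).

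**Figure D1:**
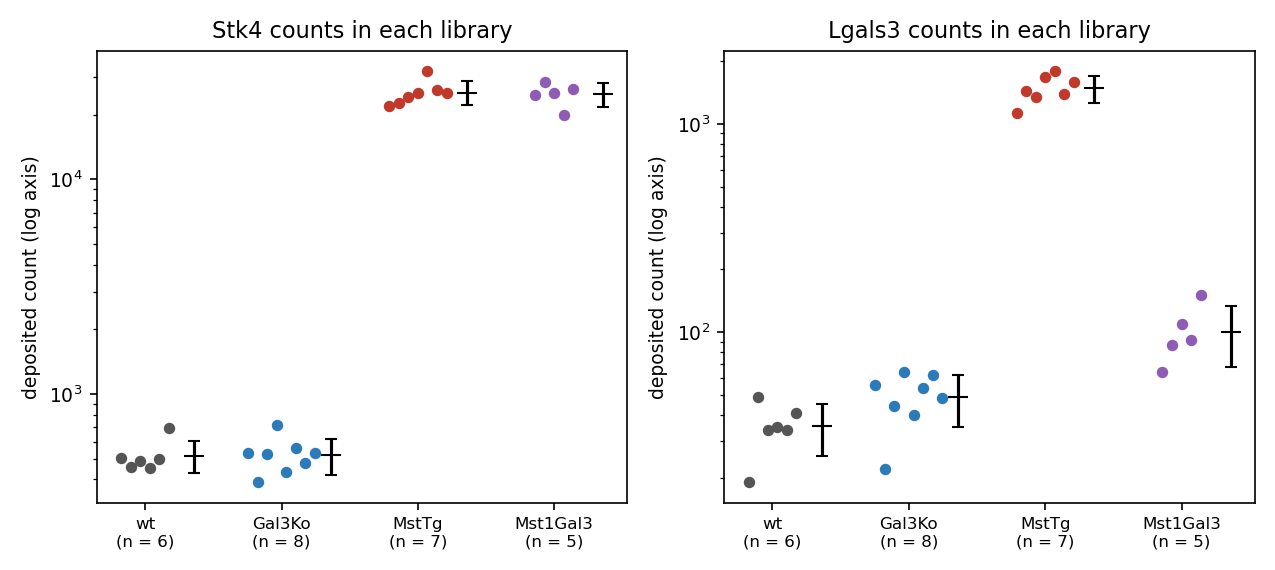
Deposited counts of Stk4 and Lgals3 (log axis) in each of the 26 libraries by group, with points for libraries and a bar for the mean ± SD of each group. Lgals3 lies at 1126 to 1791 counts in the MstTg libraries and at 64 to 151 in Mst1Gal3, while Stk4 lies at 19919 or more in every library of both groups.

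Genes of hypertrophy, heart failure and fibrosis rose with Mst-1 overexpression, and genes of energy metabolism fell. Nppa, the atrial natriuretic peptide gene that ventricles express under load, rose 31.4-fold from 73.6 CPM ± 21.8 (SD, n = 6) in wt to 2313 CPM ± 238 (n = 7) in MstTg (log2 fold change 4.97 ± 0.26 SE, adjusted p = 3.76e-14). The fetal myosin heavy chain Myh7 rose by 2.45 ± 0.31 and skeletal actin Acta1 by 3.89 ± 0.36, while Atp2a2, which encodes the calcium pump SERCA2 of the sarcoplasmic reticulum, fell by 0.92 ± 0.07 (adjusted p = 2.17e-13). The matricellular gene Postn, a marker of activated fibroblasts, rose 10-fold (3.32 ± 0.17, adjusted p = 8.75e-15), with Col1a1 (2.16 ± 0.18), Ctgf (3.04 ± 0.18) and Timp1 (2.85 ± 0.18). In total 8385 of 15249 genes differed between MstTg and wt, 4302 higher and 4083 lower, of which 1911 changed at least 2-fold (1152 higher and 759 lower). Scaled to library totals without TMM factors, an alternative chosen after seeing the data, 7789 were higher and 2166 lower, and the median change of all genes moved from 0.02 to 0.27. The changes given here are relative to the TMM scaling.

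Among called genes with a mean of at least 1 CPM and a symbol that is not a gene model name, to which the largest changes named here and in the other comparisons are limited, the largest rises included those of Mybph, a myosin-binding protein of skeletal muscle and conduction tissue (8.93 ± 0.27, from 0.0599 to 32.3 CPM), Thbs4, a matricellular protein of stressed heart (6.34 ± 0.21, from 5.91 to 481 CPM), and the Wnt and FGF receptor modulator Shisa3 (6.85 ± 0.12, from 0.840 to 97.9 CPM). Like Mybph, the genes Chodl (8.47), Muc15 (7.99), Atp1b4 (6.81), Tnmd (6.80) and Ces5a (6.67) rose from means below 0.1 CPM in wt, so the folds of all 6 are loosely bounded. The largest falls were those of Lgi1 (-6.11 ± 0.25), of Scn4b, an auxiliary subunit of the cardiac sodium channel (-5.68 ± 0.25, from 69.5 to 1.34 CPM), and of the organic cation transporter Slc22a3 (-5.55 ± 0.18). Ptprn2 (-5.54 ± 1.27, adjusted p = 0.000695) rested on wt replicates 5 (725 counts) and 6 (495), since the other wt libraries had 2 to 5 counts and MstTg 3 to 7. It lost its call by limma-voom (0.300) and with quality weights (0.239). The calcium channel subunit Cacng6 (-5.43 ± 0.43), the chloride channel Clcn1 (-4.98 ± 0.23), the acyl-CoA synthetase Acsl6 (-4.96 ± 0.27) and the water channel Aqp4 (-4.44 ± 0.42) also fell.

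Fibrosis and hypertrophy genes rose as groups, and genes of oxidative metabolism fell. All 34 fibrosis and extracellular matrix genes rose, and the same 34 when adjusted over the list alone (median log2 fold change 1.99, camera adjusted p = 1.01e-22). Among them Tgfb2 rose by 1.94 ± 0.07 and the gelatinase Mmp2 by 2.07 ± 0.08. All 12 fetal and hypertrophic genes rose (12 adjusted over the list alone, median 2.56, adjusted p = 1.15e-09). They were led by Fhl1 (3.58 ± 0.08), Xirp2 (3.51 ± 0.10) and Uchl1 (4.0 ± 0.13). Of 15 fibroblast markers 13 rose and 1 fell, the same counts as adjusted over the list alone (median 0.89, adjusted p = 4.91e-07). Among these were Dcn (1.36 ± 0.07) and Mfap5 (2.69). Of 29 fatty acid oxidation genes 27 fell and none rose (28 fell adjusted over the list alone, median -1.26, adjusted p = 2.29e-20). Among these were Acaa2 (-2.14 ± 0.07) and Hadh (-1.92 ± 0.06). All 36 nuclear-encoded respiratory chain genes fell, 36 adjusted over the list alone (median -1.05, adjusted p = 1.85e-27). So did all 16 citric acid cycle genes, 16 adjusted over the list alone (median -1.10, adjusted p = 6.45e-16). Of 20 calcium handling and ion channel genes 17 fell (18 adjusted over the list alone, median -0.42, adjusted p = 2.42e-07). They included the potassium channel genes Kcnj3 (-2.98 ± 0.09), Kcnip2 (-1.83 ± 0.08) and Kcnd3 (-1.11). These 7 calls held with an estimated correlation between genes.

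Another 6 lists were called by camera with its preset correlation only. Of 21 interferon response genes 20 rose (20 adjusted over the list alone, median 1.17, adjusted p = 1.42e-06), with adjusted p = 0.296 with an estimated correlation. Among them Irf7, the transcription factor that amplifies interferon signalling, rose by 1.81 ± 0.19 and Oasl2 by 1.48 ± 0.15. Of 21 cell cycle genes 19 rose and 1 fell, as adjusted over the list alone (median 0.87, adjusted p = 0.000822), with adjusted p = 0.292 with an estimated correlation. The replication gene Mcm6 rose by 1.24 ± 0.09, and the mitotic gene Cenpf fell (-2.19). Of 23 YAP/TEAD target genes 13 rose and 4 fell, as adjusted over the list alone (median 0.30, adjusted p = 0.000832), with adjusted p = 0.158 with an estimated correlation. All 7 measured respiratory chain genes of the mitochondrial genome fell, 7 adjusted over the list alone (median -1.34, adjusted p = 7.08e-06), with adjusted p = 0.177 with an estimated correlation. Of 21 glycolysis and glucose uptake genes 2 rose and 15 fell, as adjusted over the list alone (median -0.38, adjusted p = 0.000137), with adjusted p = 0.296 with an estimated correlation. Here the glucose transporter Slc2a1 rose by 1.67 ± 0.07, while the insulin-responsive transporter Slc2a4 (-0.88) and the lactate dehydrogenase subunit Ldhb (-1.41) fell. Of 14 endothelial markers 11 fell (12 adjusted over the list alone, median -0.37, adjusted p = 0.00119), with adjusted p = 0.209 with an estimated correlation.

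Camera did not call the other fixed lists in MstTg against wt, so they were not shown to move relative to other genes. Fry, which makes no such comparison, called 24 of the 31 lists. Among those that camera left out were p53 and apoptosis genes (fry adjusted p = 9.64e-09, upward), Hippo pathway components (1.04e-08, upward), neutrophil markers (2.54e-08, downward), the integrated stress response (5.54e-06, upward), galectins (6.91e-06, upward) and inflammatory mediators (0.0107, upward). Of 24 macrophage markers 6 rose and 2 fell (5 and 2 adjusted over the list alone, median 0.01, adjusted p = 0.668). Gpnmb, a marker of lipid-laden and reparative macrophages, rose by 2.15 ± 0.19 and Cd68 by 1.11 ± 0.14, in contrast to Cd163, a resident macrophage marker, which fell by 0.85. The pan-macrophage gene Adgre1 was at 0.08 (adjusted p = 0.591). Of 19 inflammatory mediators 7 rose and 3 fell, as adjusted over the list alone, with a median of -0.02, a mean of 0.26 and an upward test (adjusted p = 0.478). Within this list Cxcl10 rose by 3.60 ± 0.33 and Ccl2, the monocyte chemoattractant, fell by 0.94 ± 0.23. Of 8 NADPH oxidase subunits 2 rose, among them Nox4 (3.01 ± 0.17), with a median of -0.04, a mean of 0.36 and an upward test (adjusted p = 0.765). Of 19 integrated stress response genes 10 rose and 3 fell (adjusted p = 0.0669), with Atf3 up by 5.35 ± 0.33. Of 18 sarcomere genes 4 rose and 8 fell (median -0.08, adjusted p = 0.177), including Tnni3 (-1.20 ± 0.08) and Myl2 (-0.85). Myh6, the adult myosin heavy chain, was lower by 0.20 ± 0.08 (-0.20, adjusted p = 0.0359). The call ended without wt replicate 2 (adjusted p = 0.0633) or 5 (0.123) and without MstTg replicate 1 (0.0853), 2 (0.0605), 3 (0.0674) or 7 (0.0763). It also ended with the replicate number as a block. The sign of Myh6 turned under library totals (0.04, adjusted p = 0.686). In counts that were equal when adjusted over the list alone, 12 of 19 Hippo pathway components rose and 2 fell (adjusted p = 0.0810). With equal counts too, 5 of 21 antioxidant genes rose and 8 fell (adjusted p = 0.416), and 4 of 17 autophagy and lysosome genes rose and 4 fell (adjusted p = 0.873). Of 18 p53 and apoptosis genes 11 rose and 3 fell (4 adjusted over the list alone, adjusted p = 0.130). In the list of other galectins and the galectin-3 binding protein Lgals3bp (6 measured), 5 rose and 1 fell, with a median of 0.29, a mean of -0.00 and an upward test (adjusted p = 0.239). Here Lgals9 rose by 0.53 ± 0.09 and Lgals3bp by 0.81 ± 0.13. Among lists of other cell types, 2 of 12 smooth muscle and pericyte markers rose and 6 fell (adjusted p = 0.239). Of 5 red blood cell genes 0 changed by edgeR or by their list test (adjusted p = 0.767), and 2 of 8 atrial markers rose and 1 fell (adjusted p = 0.446). The tests for 5 mesothelial (adjusted p = 0.869), 5 Schwann cell (adjusted p = 0.781) and 3 neutrophil markers (adjusted p = 0.147) gave no call either. Neither did those for 14 circadian clock genes (adjusted p = 0.765) and 10 immediate early genes (5 rose, 6 adjusted over the list alone, adjusted p = 0.0559).

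**Figure D2:**
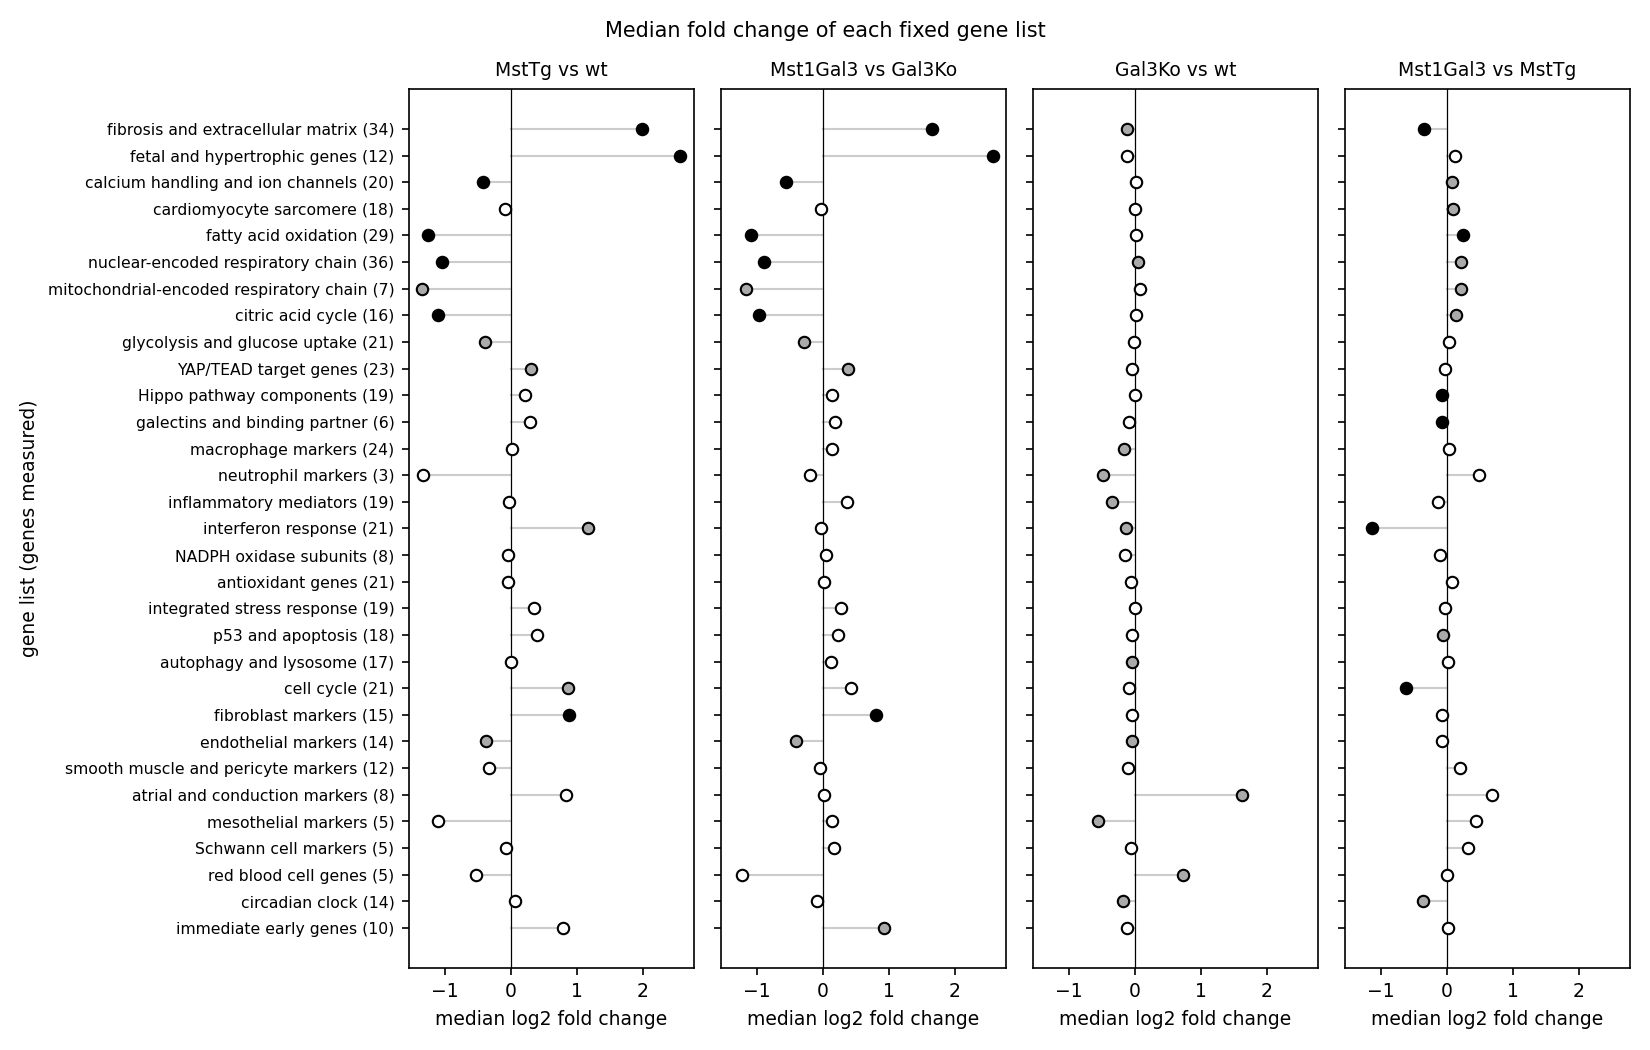
Median log2 fold change of each of the 31 tested gene lists in the 4 pairwise comparisons, with black points for lists called by camera at both correlation settings, grey for the preset correlation only and white for lists not called. The interferon response list lies at 1.17 in MstTg against wt, at -1.14 in Mst1Gal3 against MstTg and at -0.03 in Mst1Gal3 against Gal3Ko.

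Loss of galectin-3 alone left the ventricle close to wild type, and most genes that did change lay on the chromosome of Lgals3. The proteasome subunit Psmb5 fell by 1.02 ± 0.12 (adjusted p = 1.09e-05) and the ribonuclease Ang by 2.03 ± 0.23 (adjusted p = 1.19e-06). The glycogen phosphatase subunit Ppp1r3e fell by 1.70 ± 0.18 (adjusted p = 3.73e-07) and the tyrosine kinase Ptk2b by 1.27 ± 0.17 (adjusted p = 8.58e-05). The ubiquitin ligase Trim13 (-1.30 ± 0.19), the interferon-inducible gene Epsti1 (-1.09 ± 0.20) and Wdfy4, which acts in antigen cross-presentation (-0.91 ± 0.15, but adjusted p = 0.0582 without the 6 libraries in which 4 atrial genes together exceeded 30 CPM), also fell. All 7 are on chromosome 14. Among genes that rose, the light-sensing opsin Opn4 (1.48 ± 0.21) is on chromosome 14, while the leukotriene enzyme Alox5 (0.53 ± 0.08, adjusted p = 0.000197) and the monocarboxylate transporter Slc16a7 (0.54 ± 0.10, adjusted p = 0.00650) are elsewhere. Myh7, on chromosome 14 at 7.61 Mb from Lgals3, rose 2.72-fold from 302 CPM ± 175 (SD, n = 6) to 821 CPM ± 95.5 (n = 8) (1.44 ± 0.29, adjusted p = 0.0191). The Myh7 call ended without wt replicate 1 (adjusted p = 0.0505), 3 (0.0703) or 6 (0.0698) and in a fit of these groups alone (0.160). It also ended with the replicate number as a block.

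In total 54 genes differed between Gal3Ko and wt, 27 higher and 27 lower, and 18 changed at least 2-fold. Under library totals 16 were higher and 45 lower, of 61. DESeq2 called 89. A fit of these groups alone called 33, as did a fit without those 6 libraries, and 14 remained without the genes of chromosome 14, 11 higher and 3 lower. Of the 53 called genes with a known position 30 are on chromosome 14 and 23 elsewhere, so this fit also ended calls of genes on other chromosomes. The potassium channel subunit Kcne1 rose (0.97 ± 0.20, adjusted p = 0.0158). Its call ended without wt replicate 3 (0.0562), without those 6 libraries (0.0938) and with the replicate number as a block. Ankrd35 fell (-0.72 ± 0.15, adjusted p = 0.0151) except without wt replicate 3 (0.0528) or 4 (0.0748), in a fit of these groups alone (0.123), by limma-voom (0.0588) or without the 6 (0.0938). Rph3al rose (0.51 ± 0.12, adjusted p = 0.0343), a call that ended without any of wt replicates 2 to 6 and Gal3Ko replicates 1 and 4 to 8 (adjusted p from 0.0522 to 0.112). The replicate number as a block ended the Rph3al call too.

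The RNA component of ribonuclease P has annotated copies, Rprl2 (chromosome 3) and Rprl3 (chromosome 8), that were almost absent in wt and MstTg. Rprl3 had 0 to 2 counts per library in wt and 0 to 3 in MstTg, against 667 to 1828 in Gal3Ko and 660 to 2369 in Mst1Gal3. Rprl2 had 3 counts in all of wt and 615 in all of Gal3Ko, a ratio of 143 (95% interval 48.7 to 696). It had 3 in MstTg against 467 in Mst1Gal3, a ratio of 218 (74.2 to 1062), intervals that cover counting error only. The parent gene Rpph1, on chromosome 14 at 3.43 Mb from Lgals3, had 26557 to 67132 counts in wt and 18178 to 59897 in Gal3Ko, far above either copy.

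Groups of genes moved little with galectin-3 loss alone, and of all list members only Myh7 and the mitophagy receptor Bnip3l (-0.30 ± 0.06, adjusted p = 0.00659), both on chromosome 14, were called. Camera called 12 of 31 lists with its preset correlation, and 0 with an estimated correlation or by fry, with 1015 genes at an unadjusted p under 0.05 by edgeR. Inflammatory mediators had the smallest p of these (median -0.34, 0 fell, 5 fell adjusted over the list alone, adjusted p = 0.000222), with adjusted p = 0.299 with an estimated correlation. Fibrosis genes had a median of -0.12 (0 fell, 0 adjusted over the list alone, adjusted p = 0.00525) and adjusted p = 0.596 with an estimated correlation. They lost the call without wt replicate 4 (0.474). Without that library the nuclear-encoded respiratory chain (median 0.04, adjusted p = 0.00525) lost its call too (0.0990), with adjusted p = 0.614 with an estimated correlation. Macrophage markers (median -0.16, adjusted p = 0.00735) lost it without wt replicate 2 (0.171) or 4 (0.347). Interferon genes (median -0.13, adjusted p = 0.00766) did so without wt replicate 3 (0.0599) or 4 (0.130). The adjusted p of these lists was 0.596 and 0.627 with an estimated correlation. The number of lists called was 19 without wt replicate 1, 7 without wt replicate 3 and 4 without wt replicate 4. Atrial and conduction markers lay higher in Gal3Ko (median 1.63, adjusted p = 0.00735, adjusted p = 0.580 with an estimated correlation), with adjusted p = 0.0513 without the 6 libraries in which 4 of these genes exceeded 30 CPM. Red blood cell genes lay at 0.73 (adjusted p = 0.0258, adjusted p = 0.590 with an estimated correlation), a call that ended without wt replicate 3, 4 or 6 or Gal3Ko replicate 1 or 6 (adjusted p from 0.0727 to 0.124).

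Camera calls of 5 more lists in Gal3Ko against wt were marginal, and each ended without any 1 of several libraries. Autophagy and lysosome genes (median -0.04, adjusted p = 0.0409, and adjusted p = 0.590 with an estimated correlation) lost the call without wt replicate 2, 4 or 6, without Gal3Ko replicate 1, 6, 7 or 8 (adjusted p from 0.0610 to 0.215) and without chromosome 14 (0.192). Endothelial markers (median -0.04, adjusted p = 0.0187, and adjusted p = 0.580 with an estimated correlation) lost it without wt replicate 3, 4 or 5 or Gal3Ko replicate 2 or 3 (0.0504 to 0.170). Circadian clock genes (median -0.18, adjusted p = 0.0258, and adjusted p = 0.580 with an estimated correlation) lost it without wt replicate 4 or 5 or Gal3Ko replicate 1, 3 or 4 (0.0607 to 0.130). The 3 neutrophil markers (median -0.48, adjusted p = 0.0385, and adjusted p = 0.299 with an estimated correlation) lost it without wt replicate 3, 5 or 6 or Gal3Ko replicate 1, 3, 4, 7 or 8 (0.0568 to 0.0873). The 5 mesothelial markers (median -0.56, adjusted p = 0.0458, and adjusted p = 0.580 with an estimated correlation) lost it without wt replicate 2, 3, 5 or 6, Gal3Ko replicate 4, 7 or 8, MstTg replicate 7 or Mst1Gal3 replicate 4 (0.0510 to 0.161).

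In the Mst-1 background, the interferon response genes fell with galectin-3 loss to about their level in wt, and part of the fibrosis genes fell. All 21 interferon response genes fell (21 adjusted over the list alone, median log2 fold change -1.14, adjusted p = 6.13e-46, held with an estimated correlation at adjusted p = 0.0102). Irf7 fell 3.96-fold, from 22.1 CPM ± 7.79 (SD, n = 7) in MstTg to 5.56 CPM ± 0.690 (n = 5) in Mst1Gal3 (-1.99 ± 0.21, adjusted p = 9e-07), near its wt level of 6.28 CPM ± 1.54 (n = 6). The antiviral genes Ifit1 (-1.85 ± 0.21), Ifit3 (-1.74 ± 0.21), Oasl1 (-1.80 ± 0.26) and Zbp1 (-1.79 ± 0.28) fell, as did the deISGylase Usp18 (-1.48 ± 0.17) and the RNA sensor Ifih1 (-0.78 ± 0.09). The mean log2 CPM of the list was 3.38 ± 0.37 (SD) in MstTg, from 2.99 to 3.99, and 2.20 ± 0.09 in Mst1Gal3, from 2.11 to 2.34, against 2.31 ± 0.22 in wt and 2.12 ± 0.17 in Gal3Ko. Macrophage markers did not move alongside, with 0 of 24 called by edgeR and a median of 0.04 (adjusted p = 0.855). Of the 3 measured neutrophil markers 1 rose (1 adjusted over the list alone, median 0.48), a list that fry called (adjusted p = 0.00113) and camera did not (0.0539). Their mean log2 CPM was -0.86 ± 0.15 (SD) in MstTg, -0.16 ± 0.07 in Mst1Gal3 and 0.40 ± 0.15 in wt.

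Of 34 fibrosis and extracellular matrix genes 10 fell and none rose (20 fell adjusted over the list alone, median -0.35, adjusted p = 2.25e-19, held with an estimated correlation at adjusted p = 0.0430). Postn fell 1.69-fold (-0.76 ± 0.16, adjusted p = 0.00593), from 425 CPM ± 41.3 (SD, n = 7) to 251 CPM ± 59.8 (n = 5), still above the wt level of 42.5 CPM ± 14 (n = 6). Collagen XIV Col14a1 (-0.88 ± 0.13), the crosslinking enzyme Loxl2 (-0.73 ± 0.12), Thbs4 (-0.84 ± 0.16) and Mmp2 (-0.40 ± 0.08) fell too. Of these, Loxl2 lies on chromosome 14, at 22.28 Mb from Lgals3. The fibrillar collagens Col1a1 (-0.27, adjusted p = 0.461) and Col3a1 (-0.32, adjusted p = 0.139) and fibronectin Fn1 (-0.38, adjusted p = 0.0648) did not pass. Mst1Gal3 replicate 4 stood apart in Col1a1 (737 CPM, others 426 to 494), and without it Col1a1 was at -0.43 (adjusted p = 0.225) and Col3a1 passed (-0.44, adjusted p = 0.0342). Fn1 did so without wt replicate 4 (0.0136) or 5 (0.0486), by DESeq2 (0.0327) and in a fit of these groups alone (0.0186). Of 15 fibroblast markers 1 fell (2 rose and 2 fell adjusted over the list alone, median -0.08, adjusted p = 0.147), the elastic fibre gene Mfap5 (-0.64 ± 0.13).

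**Figure D3:**
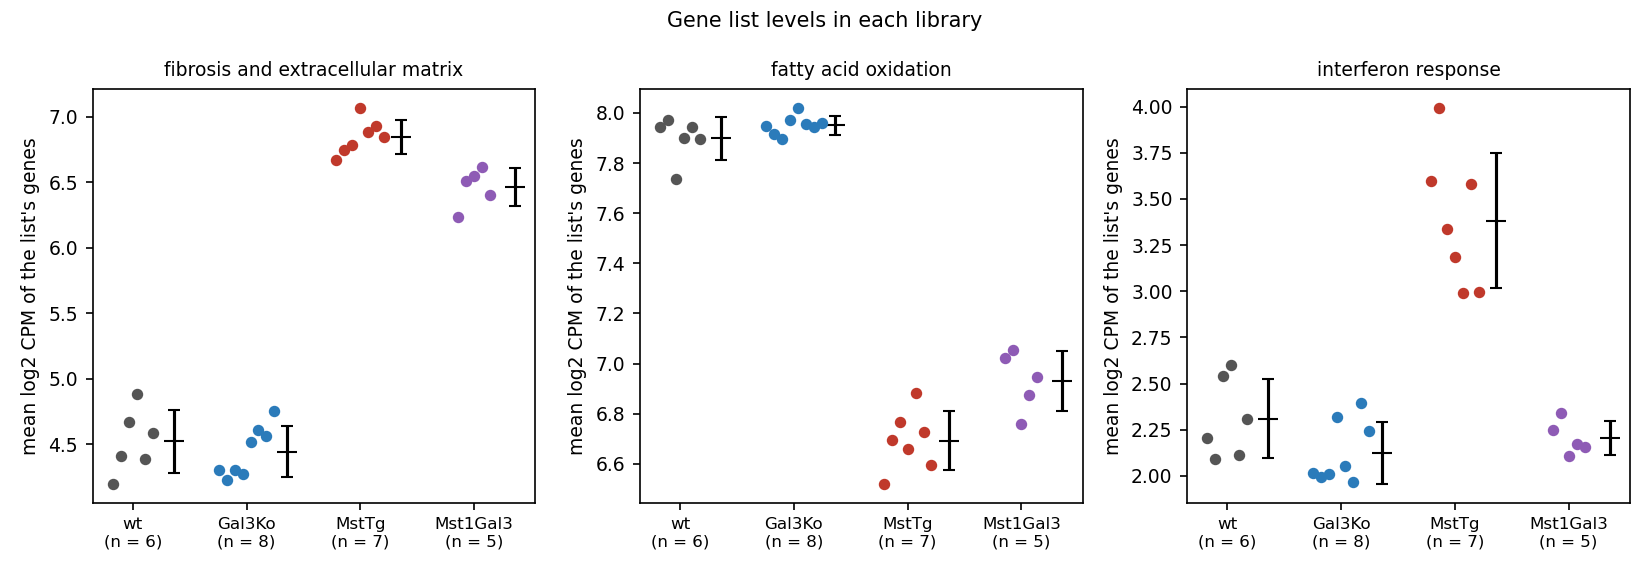
Mean log2 CPM of the fibrosis, fatty acid oxidation and interferon response lists in each library by group, with points for libraries and a bar for the mean ± SD. The interferon mean is 3.38 ± 0.37 in MstTg and 2.20 ± 0.09 in Mst1Gal3, while the fibrosis mean is 6.85 ± 0.13 and 6.46 ± 0.15 against 4.52 ± 0.24 in wt.

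Fatty acid oxidation genes moved part of the way back towards wild type, whereas the other metabolic lists did not hold with an estimated correlation or were not called. Of 29 fatty acid oxidation genes 14 rose (22 adjusted over the list alone, median 0.24, adjusted p = 6.29e-14, held with an estimated correlation at adjusted p = 0.0430). Among these were Acaa2 (0.48 ± 0.07) and the fatty acid carrier Fabp3 (0.28 ± 0.06). Their mean log2 CPM was 6.69 ± 0.12 in MstTg, 6.93 ± 0.12 in Mst1Gal3 and 7.90 ± 0.09 in wt. Of 36 nuclear-encoded respiratory chain genes 15 rose (34 adjusted over the list alone, median 0.21, adjusted p = 2.25e-19), with adjusted p = 0.0706 with an estimated correlation. Among them were Cox7a1 (0.45 ± 0.09) and Ndufa5 (0.35 ± 0.07). Of 16 citric acid cycle genes 2 rose (6 adjusted over the list alone, median 0.14, adjusted p = 5.17e-05), with adjusted p = 0.326 with an estimated correlation. Of 21 glycolysis genes 2 rose (2 adjusted over the list alone, median 0.03, adjusted p = 0.101). Of 21 cell cycle genes 5 fell (16 adjusted over the list alone, median -0.62, adjusted p = 8.98e-13, held with an estimated correlation at adjusted p = 0.0430). They included the replication genes Mcm2 (-0.76 ± 0.10), Mcm5 (-0.70 ± 0.16) and Rrm2 (-0.86 ± 0.19). Among 6 galectins and binding partner Lgals9 (-0.73 ± 0.09) and Lgals3bp (-0.88 ± 0.14) fell (2 adjusted over the list alone, median -0.07, adjusted p = 0.00527, held at adjusted p = 0.0430). Of 19 Hippo pathway components 2 fell (2 adjusted over the list alone, median -0.08, adjusted p = 0.00820, held at adjusted p = 0.0430), among them the TEAD factor Tead4 (-0.52 ± 0.12).

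The fetal and hypertrophic genes did not change as a group, with 0 of 12 called by edgeR, 0 adjusted over the list alone, and a median of 0.12, a mean of -0.01 and a downward test (adjusted p = 0.919). Nppa was at -0.62 ± 0.23 (adjusted p = 0.129). It passed in a fit of these groups alone (-0.64, adjusted p = 0.0102) and with quality weights (0.0391). Myh7 was at -0.66 ± 0.30 (adjusted p = 0.248). Myh6 rose by 0.41 ± 0.09 (adjusted p = 0.00298). Atp2a2 was at 0.23 ± 0.07 (adjusted p = 0.0530). It passed without MstTg replicate 5 (0.0204), Gal3Ko replicate 2 (0.0429), 4 (0.0439) or 7 (0.0445) or Mst1Gal3 replicate 3 (0.0481) or 5 (0.0282), and by DESeq2 (0.0201) and limma-voom (0.0339). The potassium channel gene Kcnj3 rose by 0.69 ± 0.10. In its list of calcium handling and ion channel genes 3 of 20 rose (4 adjusted over the list alone, median 0.07, adjusted p = 0.0398), with adjusted p = 0.326 with an estimated correlation. This call ended without MstTg replicate 2 (0.0595) or 4 (0.0630) or Mst1Gal3 replicate 1 (0.0731) or 2 (0.0626) or under library totals (0.0651). Of 18 sarcomere genes 3 rose (5 adjusted over the list alone, median 0.09, adjusted p = 0.00668), with adjusted p = 0.463 with an estimated correlation and 0.135 without chromosome 14, where Myh6 and Tnnc1 (0.51 ± 0.10) lie.

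Camera also called 3 lists that did not hold, all of which lost the call in other settings. The 7 respiratory chain genes of the mitochondrial genome (1 rose, 1 adjusted over the list alone, median 0.21, adjusted p = 0.0114, adjusted p = 0.463 with an estimated correlation) lost it without Mst1Gal3 replicate 2 (0.0514) or 5 (0.104) and without the 6 libraries with atrial genes over 30 CPM (0.131). The p53 and apoptosis genes (1 of 18 fell, 1 adjusted over the list alone, median -0.06, adjusted p = 0.0178, adjusted p = 0.101 with an estimated correlation) lost it without Mst1Gal3 replicate 1 (0.0515). Circadian clock genes (0 of 14 called, 1 rose and 3 fell adjusted over the list alone, median -0.36, adjusted p = 0.0398, adjusted p = 0.284 with an estimated correlation) lost it without MstTg replicate 1 (0.0528), 2 (0.0603) or 5 (0.0797) or Mst1Gal3 replicate 2 (0.0677) or 4 (0.07). They also lost it under library totals (0.191), without chromosome 14 (0.0664) and with the kidney covariate (0.0634). Inflammatory mediators (median -0.13, adjusted p = 0.101), YAP/TEAD targets (-0.03, adjusted p = 0.0977), NADPH oxidase subunits (-0.11, adjusted p = 0.0539, with Nox4 lower by 0.68 ± 0.15, -0.68) and the integrated stress response (-0.03, adjusted p = 0.336) were called neither by camera nor by fry. Fry did not call the sarcomere (0.113), the 7 mitochondrial (0.133) and the circadian genes (0.0975) either.

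In total 746 genes differed between Mst1Gal3 and MstTg, 387 higher and 359 lower, of which 87 changed at least 2-fold (33 higher and 54 lower). Without Mst1Gal3 replicate 1 the count was 469. Without MstTg replicate 5 it was 1040, 60.7% of them higher, and without the 6 libraries with atrial genes over 30 CPM it was 1027, 647 higher and 380 lower. Under library totals 136 were higher and 558 lower, of 694. Apart from Lgals3 and the interferon genes, the largest falls were those of Arhgap22, a Rac GTPase-activating protein on chromosome 14 (-2.56 ± 0.12, adjusted p = 1.4e-15, from 18.7 CPM ± 2.46 to 3.17 CPM ± 0.432), and the class I histocompatibility gene H2-Q6 (-1.62 ± 0.25). Within the same limits of level and symbol, the largest rises after Rprl2 and Rprl3 were those of the calcium-activated potassium channel Kcnma1 on chromosome 14 (1.99 ± 0.29), Opn4 (1.52 ± 0.26), the mitochondrial threonine transfer RNA mt-Tt (1.48 ± 0.31), the enkephalin precursor Penk (1.53 ± 0.28) and the aminopeptidase Lvrn (1.45 ± 0.31). Cdh22 (1.63 ± 0.41, adjusted p = 0.0184) lost its call without Mst1Gal3 replicate 4 (0.0615) or 5 (0.0503) and by limma-voom (0.0561).

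Genes that changed with galectin-3 loss in both backgrounds clustered around Lgals3. Of the 769 genes called in either comparison, 70.2% changed in the same direction in both, against 50.8% of all 15247 genes other than the targets. The share was 60.6% under library totals and 68.2% with chromosome 14 left out, so this agreement in direction was not confined to that chromosome. The 30 genes called in both all had the same sign, 14 higher where 0.685 would be shared by chance and 16 lower where 0.634 would. Of the 29 of these with a known position, 20 (69.0%, exact 95% interval 49.2 to 84.7) lay within 20 Mb of Lgals3, against 274 of 15193 genes tested (1.80%, Fisher's exact p = 5.71e-29, two-sided). Among all calls the share in that window was 25 of 53 in Gal3Ko against wt (47.2%, Fisher's exact p = 4.82e-30). It was 50 of 743 in Mst1Gal3 against MstTg (6.73%, Fisher's exact p = 4.13e-16), but 1.76% in MstTg against wt (Fisher's exact p = 0.668). Of the genes with an interaction 9 of 99 lay in the window (9.09%, Fisher's exact p = 7.43e-05) and 12 on chromosome 14. Alox5 on chromosome 6 and the lipocalin Apod on chromosome 16 (-0.46 and -0.87) were among the 7 shared genes off chromosome 14, with Rprl2, Rprl3, Gm6768, Gm10704 and Gm3375. Of these Apod and the 3 gene models were named after their values were seen. Rprl2 and Rprl3 are annotated copies of Rpph1, which lies in the window, and the origin of their reads was not examined. Irf9, a subunit of the interferon-activated ISGF3 complex, also lies in the window, at 8.23 Mb from Lgals3 (chromosome 14, 55603571 to 55610030). Irf9 was at 13.9 CPM ± 1.55 (SD, n = 6) in wt, 13.6 CPM ± 2.03 (n = 8) in Gal3Ko, 22.6 CPM ± 3.30 (n = 7) in MstTg and 12.9 CPM ± 0.869 (n = 5) in Mst1Gal3.

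**Figure D4:**
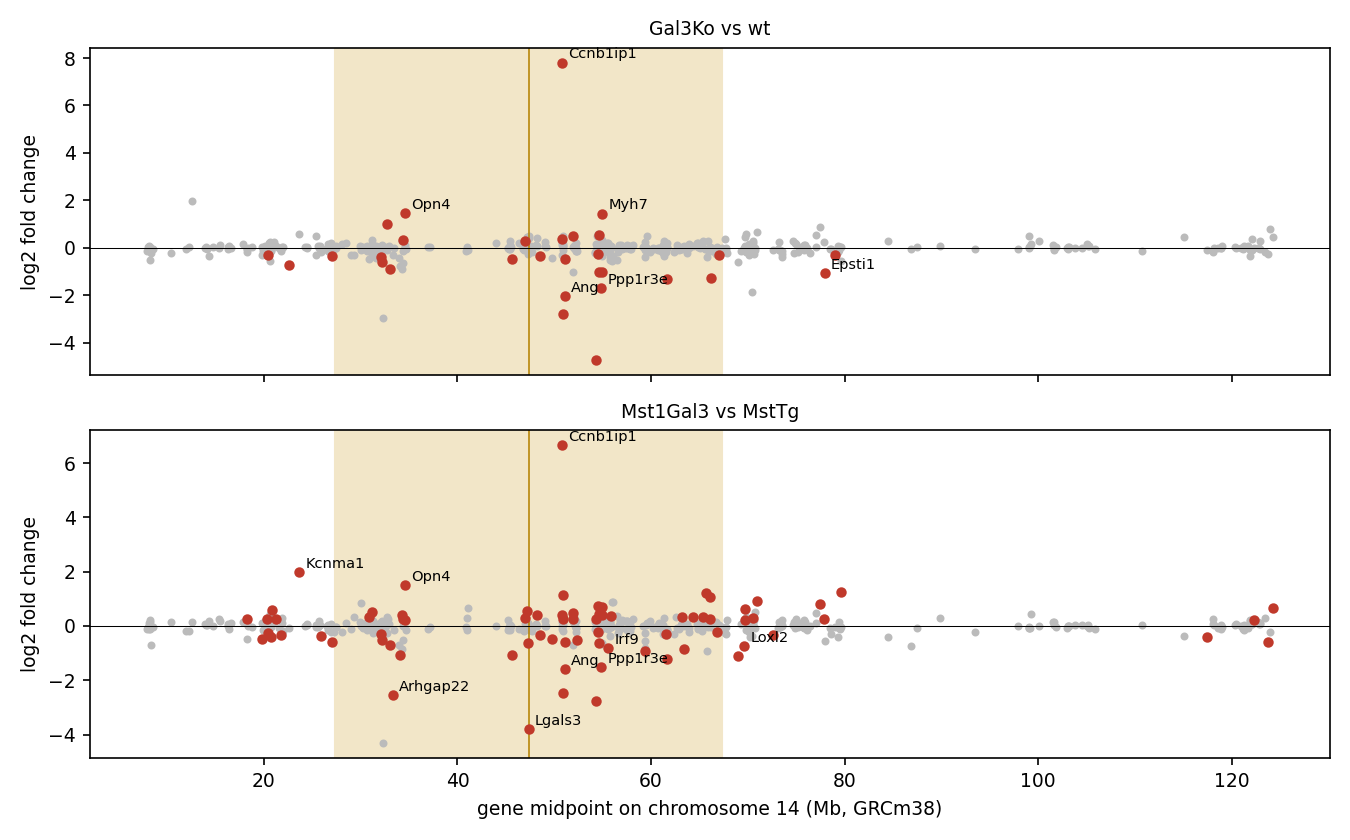
Log2 fold change against gene midpoint on chromosome 14 (Mb, GRCm38) for Gal3Ko against wt and Mst1Gal3 against MstTg, with red points for called genes, grey for others, a line at Lgals3 and shading for 20 Mb either side. The called genes cluster in the shaded window, which holds 25 of 53 calls in Gal3Ko against wt, and fitted folds of genes with 0 counts in a group, such as Ccnb1ip1, carry no bound.

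Most of the Mst-1 response was also present in the galectin-3 knockout. Nppa rose 21.1-fold (4.40), to 1500 CPM ± 400 (SD, n = 5) from 71.0 CPM ± 28.6 (n = 8), and Acta1 by 5.39. Postn rose by 2.70, Col1a1 by 2.08 and Ctgf by 2.86 ± 0.16, while Atp2a2 fell by 0.69 ± 0.07 (adjusted p = 4.88e-10). Myh7 was at 0.35 (adjusted p = 0.322, but 0.00178 in a fit of these groups alone) and Myh6 at -0.11 (adjusted p = 0.299). In total 8013 genes differed between Mst1Gal3 and Gal3Ko, 4108 higher and 3905 lower, with 1675 at least 2-fold (1093 higher and 582 lower). Under library totals 7374 were higher and 1929 lower, with the median of all genes moving from 0.01 to 0.24. Mybph (9.07 ± 0.25), Atp1b4 (8.33), Muc15 (8.07), Chodl (7.66), Ces5a (7.04), Tdrd9 (6.78), Tnmd (6.60) and the glutamate receptor subunit Grin2a (6.56 ± 0.22) rose most. Lgi1 (-5.33), Clcn1 (-5.00), Slc22a3 (-4.82), Aqp4 (-4.66), Epn3 (-4.14), Scn4b (-4.01 ± 0.25) and Lrrc4b (-3.99) fell most. The fall of Ogdhl on chromosome 14 (-5.24 ± 1.30, adjusted p = 0.00160, but 0.107 by limma-voom) was carried by Gal3Ko replicates 2 (1450 counts) and 3 (1830). The other 6 Gal3Ko libraries had 26 to 99 Ogdhl counts, against 11 to 20 in Mst1Gal3.

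The lists again showed fibrosis and oxidative metabolism moving apart. All 34 fibrosis genes rose (34 adjusted over the list alone, median 1.65, adjusted p = 7.74e-22). So did 11 of 12 fetal and hypertrophic genes (11 adjusted over the list alone, median 2.57, adjusted p = 8.59e-10) and 13 of 15 fibroblast markers (13 adjusted over the list alone, median 0.81, adjusted p = 1.94e-07). In the other direction 28 of 29 fatty acid oxidation genes fell (28 adjusted over the list alone, median -1.08, adjusted p = 3.59e-19), with all 36 nuclear-encoded respiratory chain genes (36 adjusted over the list alone, median -0.89, adjusted p = 5.85e-26). So did all 16 citric acid cycle genes (16 adjusted over the list alone, median -0.97, adjusted p = 7.89e-16) and 17 of 20 calcium handling and ion channel genes (18 adjusted over the list alone, median -0.56, adjusted p = 1.98e-07). These 7 calls held with an estimated correlation. Calls of 5 lists did not. Among these were 7 mitochondrial-encoded genes (all fell, median -1.17, adjusted p = 0.213 with an estimated correlation) and glycolysis (2 rose and 15 fell of 21, median -0.28, adjusted p = 0.543). The others were YAP/TEAD targets (14 rose and 4 fell of 23, median 0.38, adjusted p = 0.124), endothelial markers (10 of 14 fell, median -0.40, adjusted p = 0.304) and immediate early genes (6 of 10 rose, median 0.93, adjusted p = 0.684, and no call under library totals at adjusted p = 0.148).

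The interferon response as a list was not called with Mst-1 in the galectin-3 knockout. Of its 21 genes 2 rose and 2 fell in Mst1Gal3 against Gal3Ko (1 and 1 adjusted over the list alone), with a median of -0.03, a mean of 0.07 and a downward test (adjusted p = 0.978). Ifit2 rose by 0.46 ± 0.14 and Rsad2 was lower by 0.74 ± 0.17 (-0.74, adjusted p = 0.000762). Oasl2 (0.42, adjusted p = 0.0224) lost its call without Mst1Gal3 replicate 1 (0.0551). Camera did not call the cell cycle list either (7 rose and 1 fell of 21, median 0.42, adjusted p = 0.254, fry adjusted p = 0.0133). Nor did it call macrophage markers (5 rose and 2 fell of 24, median 0.14, adjusted p = 0.344), although Cd68 rose by 1.47 ± 0.14. Inflammatory mediators (8 rose and 1 fell of 19, median 0.37, adjusted p = 0.254, fry adjusted p = 0.000396) included Cxcl10, which rose by 4.34 ± 0.32.

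Across the 8383 genes called in MstTg against wt, targets left out, the Mst-1 response in the galectin-3 knockout had a slope of 0.897 on the response outside it (Pearson r = 0.961, Spearman rho = 0.953), and 97.2% of these genes had the same sign. The slope of the response outside the knockout on that in it was 1.03. Over all 15247 genes the slope was 0.893 (r = 0.937, rho = 0.871). Both comparisons called 3423 of the same genes as higher, where 1158 would be shared by chance, and 3209 as lower, where 1046 would. These correlations are across genes, which are not independent replicates, and the comparisons share no library.

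**Figure D5:**
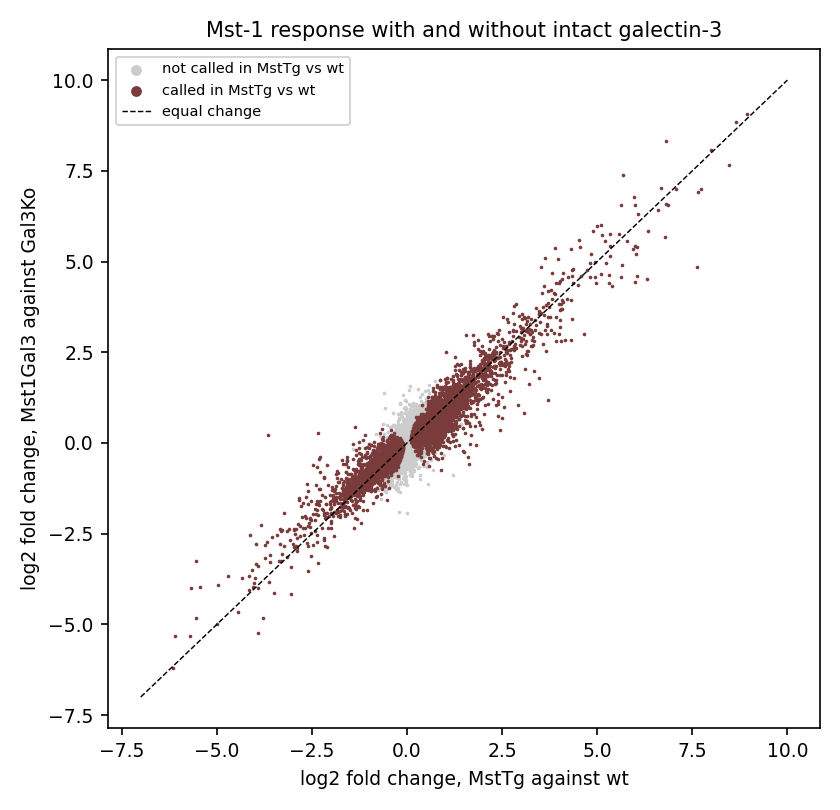
Log2 fold change of Mst1Gal3 against Gal3Ko plotted on that of MstTg against wt, with a point for each of 15247 genes and a dashed line of equal change. Genes follow the line with a slope of 0.893 over all genes and 0.897 over those called in MstTg against wt.

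The test of the interaction asks whether the Mst-1 response itself differed in the galectin-3 knockout. Of 16 lists that camera called, the interferon response and the 3 measured neutrophil markers held with an estimated correlation. All 21 interferon genes had a lower Mst-1 response (21 fell adjusted over the list alone and 13 over all genes, median -0.94, adjusted p = 7.92e-31), with adjusted p = 0.0436 with an estimated correlation. Of the neutrophil markers 1 had a higher response (2 rose adjusted over the list alone, median 1.15, adjusted p = 0.00386), also with adjusted p = 0.0436 with an estimated correlation. Irf7 had an interaction of -1.87 ± 0.29 (adjusted p = 0.00224) and Ifit1 of -1.67 (adjusted p = 0.00844, 0.0691 with quality weights). The RNA sensor Ddx58 had -0.68 (adjusted p = 0.00844) and Irf9 -0.78 ± 0.14 (adjusted p = 0.00844). Lgals3 itself had -4.22 ± 0.21 (adjusted p = 1.32e-14), Arhgap22 -2.24 ± 0.19 (adjusted p = 2.69e-09) and the CCN family matricellular gene Wisp1 -1.69 ± 0.24 (adjusted p = 0.000261). The scavenger receptor Scara5 on chromosome 14 had 1.25 ± 0.16 (adjusted p = 0.000104), the chemokine Cxcl14 1.28 ± 0.23 and the BMP modulator Bmper 1.11 ± 0.21. Myh7 had -2.10 ± 0.42 (adjusted p = 0.0193), with a mean of 302 CPM in wt, 1654 in MstTg, 821 in Gal3Ko and 1049 in Mst1Gal3. This Myh7 call ended with the replicate number as a block. Camera called fibrosis genes (1 fell, 8 adjusted over the list alone, median -0.21, adjusted p = 1.66e-07) and fatty acid oxidation (1 rose, 16 adjusted over the list alone, median 0.22, adjusted p = 1.18e-09). It also called cell cycle genes (1 fell, 4 adjusted over the list alone, median -0.55, adjusted p = 3.27e-07). In order these had adjusted p = 0.318, 0.145 and 0.145 with an estimated correlation, and fry called only fatty acid oxidation of the 3 (0.0287). Among single genes of these lists Mcm2 had -0.75 ± 0.14 (adjusted p = 0.00844), while Postn did not pass (-0.63, adjusted p = 0.232, though -0.80 and adjusted p = 0.0460 without wt replicate 4).

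In total 100 genes had an interaction, 44 higher and 56 lower, with the excess near Lgals3 given above. With the replicate number as a block the count was 51, 16 higher and 35 lower, of which 40 were among the 100. Without the 6 libraries with atrial genes over 30 CPM it was 106, 68 higher and 38 lower. The count was 189 without MstTg replicate 5, 63 without MstTg replicate 1, 58 without Gal3Ko replicate 7, 65 without Gal3Ko replicate 8, 59 without Mst1Gal3 replicate 1 and 52 without Mst1Gal3 replicate 4 and also without replicate 5. DESeq2 called 195.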

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

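The tests chosen after the results were seen were that of galectin-3 loss acting regardless of position, all 3 tests of the interferon genes and both tests of the kidney transcripts, with the kidney covariate, the fit without libraries with raised atrial genes, the fit without chromosome 14 and library totals among the alternatives.

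Genes that changed with galectin-3 loss in both backgrounds lay mostly around Lgals3. Loss of galectin-3 acting regardless of position, as the whole cause, is excluded by the share within 20 Mb, 69.0% of the placed genes called in both. The test of strain variants rests on the same share, so it is no separate evidence. Variants of the strain of origin near the knockout allele remain a candidate explanation, since that share exceeds the 1.80% of tested genes (Fisher's exact p = 5.71e-29, two-sided), a test that could have come out otherwise and whose prediction was written before. The labels do not give the strain of origin, and no sequence was examined. An effect of galectin-3 on single genes inside the window, or on the 7 shared genes off chromosome 14, stays open and untested. Of those 7, Rprl2 and Rprl3 are copies of Rpph1, a gene in the window, and the origin of their reads was not examined.

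The interferon response genes were lower in Mst1Gal3 than in MstTg by a median of -1.14. A few high MstTg libraries are excluded as the cause, because 7 of 7 lay above the highest Mst1Gal3 library. The macrophage median was 0.0382 (SD of the markers 0.17), so these markers as a set did not fall with the interferon genes. This argues against fewer macrophages in Mst1Gal3 hearts as the cause. Loss of a macrophage subset was not tested, and the lymphocyte list was too short to test. Loss of galectin-3 and an allele of the interval that holds Irf9 cannot be told apart, because both would separate the knockout groups from the others and the alleles of the interval were not examined in any library. The median of the interferon genes in Gal3Ko against wt, -0.13, has the sign that an allele acting in both backgrounds needs, but lost its call without wt replicate 3 (adjusted p = 0.0599) or 4 (0.130) and with an estimated correlation (0.627), and fry called 0 lists there. This sign was not particular to the interferon genes, since camera called 9 lists downward and 3 upward in that comparison. Irf9 itself was at -0.02 in Gal3Ko against wt and was not called. An effect of galectin-3 loss that needs Mst-1 may give the same values, and differences in housing or litter, which the labels do not give, were not tested.

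Transcripts of kidney, not a tissue of the labels, were counted in all 26 heart libraries: of 20 kidney genes listed before the test 18 were measured, and their summed share of counts ran from 0.00322% to 0.0239% (highest in Mst1Gal3 replicate 4), with 86 to 962 counts of Kap and 61 to 681 of Slc34a1. The kidney score did not fall as the log2 library total rose over 26 libraries (Pearson r = 0.0173, permutation p = 0.933, two-sided). Spearman rho was 0.162 (permutation p = 0.423, two-sided), and r was 0.153 without the 2 farthest libraries. This was the only relation of its family. It argues against fewer counts per library as the cause, but 26 libraries cannot exclude a weak relation. RNA or reads from kidney in every library are a candidate source, because the genes other than Cubn kept about 1 ratio to Slc34a1 (chi-square per degree of freedom 0.585 to 1.67, but 16.8 for Cubn, with 83 to 284 counts). Over all 18 genes, Cubn included, the value was low too (chi-square per degree of freedom 2.51, against a lowest value of 2.63 and a median of 6.75 in 1000 random gene sets). These sets were matched on mean count only, in a table where 8385 of 15249 genes differed between MstTg and wt. The comparison with them therefore cannot separate a common source from genes that Mst-1 left unchanged. Index exchange with other libraries and carry-over at dissection were not told apart, and no biological explanation was tested.

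Other splits of the same libraries were drawn 100 times per comparison, the real split included. Fewer than 5 of the 100 splits gave as many genes as the real one in each comparison. In MstTg against wt 1 split gave as many as the real 8385 (highest other 5103). In Mst1Gal3 against MstTg 1 gave as many as 746 (highest other 728), and in Mst1Gal3 against Gal3Ko 1 as many as 8013 (highest other 4776). Each of these was the real split, which argues against chance for these counts. In Gal3Ko against wt 2 gave as many as 54 (highest other 369), and in the interaction 2 as many as 100 (highest other 369). Chance is not excluded there, since another split gave far more genes than the real one. The interaction splits also removed the galectin-3 effect itself, so they do not represent the absence of an interaction alone. The splits with 5103, 728 and 4776 genes left 24 of the 26 libraries in place. The split of Gal3Ko and wt with 369 genes gave several times the real count. It exchanged wt replicates 2, 3 and 4 with Gal3Ko replicates 5, 7 and 8. The interaction split with 369 genes exchanged wt replicates 3, 4 and 5 with Gal3Ko replicates 3, 5 and 6. Whether a structure of the samples lies behind these splits was not tested.

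Single libraries stood apart from their group in 15 of 212 tests, where about 1 in 20, or 10.6, would by chance. In wt these were replicate 1 in the share of the 10 highest genes (44.2%, others 39.4 to 40.9), replicate 6 in Stk4 (26.1 CPM, others 22.4 to 23.7), replicate 4 in Col1a1 (213 CPM, others 97.9 to 141), replicate 3 in the mean log2 CPM of fatty acid oxidation (7.74, others 7.90 to 7.97), replicate 2 in that of the nuclear-encoded respiratory chain (8.60, others 8.39 to 8.47) and replicate 5 in that of atrial markers (1.89, others -0.61 to 0.10). In MstTg they were replicate 1 in the mitochondrial share (23.3%, others 14.4 to 18.2), replicate 5 in Atp2a2 (8304 CPM), replicate 4 in Col3a1 (651 CPM, others 492 to 555) and replicate 2 in macrophage markers (3.38, others 3.14 to 3.22). In Mst1Gal3 they were replicate 4 in Col1a1 (737 CPM, others 426 to 494), Ccl2 (0.927 CPM, others 0.70 to 0.755) and Hippo components (5.01, others 4.98 to 4.99), and replicate 5 in Adgre1 (19.7 CPM, others 12.8 to 13.7) and smooth muscle markers (5.99, others 5.87 to 5.89).

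With the replicate number as a block, the interaction calls of Myh7, Scn4b, Penk, Ptk2b, mt-Tq, Oasl1, Loxl2, Acaa2 and Mmp9 ended. In the main fit the Mst-1 response in the galectin-3 knockout minus that outside it passed the test of the interaction for the named genes that follow. It was negative for Lgals3 (-4.22), Arhgap22 (-2.24), Myh7 (-2.10), Irf7 (-1.87), Angptl7 (-1.87, adjusted p = 0.0926 with quality weights), Oasl1 (-1.71), Kcne1 (-1.69), Wisp1 (-1.69), Ifit1 (-1.67), Irf9 (-0.78), Mcm2 (-0.75), Loxl2 (-0.73), Ddx58 (-0.68) and Lgals9 (-0.60), and positive for Mmp9 (1.90), mt-Tt (1.87), Scn4b (1.68), Penk (1.49), Cxcl14 (1.28), Scara5 (1.25), Ptk2b (1.22), mt-Tq (1.11), Bmper (1.11) and Acaa2 (0.46). Calls ended without Mst1Gal3 replicate 4 for mt-Tt (adjusted p = 0.0568), Scn4b (0.0624), Mmp9 (0.0559) and Lgals9 (0.0511), without replicate 5 for mt-Tt (0.0591), Scn4b (0.0624) and Oasl1 (0.0512), without replicate 1 for Oasl1 and Mmp9 (both 0.0519), and without MstTg replicate 1 (0.0565) or 6 (0.0515) for Scn4b. Those of Loxl2 (17 libraries, 0.0569 to 0.103: Gal3Ko 1 and 5 to 8, Mst1Gal3 1, 4 and 5, MstTg 1 to 4, wt 1, 2, 3, 5 and 6), mt-Tq (17 libraries, 0.0591 to 0.134: Gal3Ko 1, 2 and 5 to 8, Mst1Gal3 2, 4 and 5, MstTg 1, 2, 4 and 6, wt 1, 2, 4 and 5) and Penk (15 libraries, 0.0540 to 0.119: Gal3Ko 1, 4, 5, 7 and 8, Mst1Gal3 1 and 5, MstTg 1, 2, 3, 4 and 6, wt 1, 2 and 5) ended without any 1 of the replicates listed.

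Camera called 16 lists in the interaction, of which interferon response (median -0.94) and the 3 measured neutrophil markers (1.15, adjusted p = 0.0436) held with an estimated correlation. Calls that no single library ended were fibrosis (-0.21), fatty acid oxidation (0.22), the nuclear-encoded respiratory chain (0.16), cell cycle (-0.55), the citric acid cycle (0.11) and Hippo components (-0.0377). Glycolysis (0.10) lost its call without Gal3Ko replicate 8 (adjusted p = 0.0550), Mst1Gal3 replicate 4 (0.0866) or MstTg replicate 1 (0.0578), antioxidant genes (0.16) and smooth muscle markers (0.26) without wt replicate 4 (both 0.0543), and mesothelial markers (1.22) without Mst1Gal3 replicate 5 (0.0678) or MstTg replicate 5 (0.0825). Atrial markers (-0.80) lost it without any of 12 libraries (Gal3Ko 4, 5 and 8, Mst1Gal3 1, 2, 4 and 5, MstTg 5 and 6, wt 1, 4 and 6; 0.0501 to 0.104), and galectins (-0.0544) without any of 13 (Gal3Ko 1 to 4, Mst1Gal3 1, 3 and 4, MstTg 1, 3, 5 and 6, wt 5 and 6; 0.0550 to 0.113). Red blood cell genes (-0.74) lost it without any of 14 (Gal3Ko 1, 2, 4 and 6, Mst1Gal3 1, 3 and 5, MstTg 1, 4 and 6, wt 1, 3, 4 and 6; 0.0553 to 0.260), and sarcomere genes (0.12) without any of 16 (Gal3Ko 1, 2, 3, 6 and 8, Mst1Gal3 1, 2 and 4, MstTg 1, 2, 4 and 7, wt 1, 2, 5 and 6; 0.0521 to 0.209).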

How the results depend on the processing

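Alternatives chosen after seeing the data were library totals without TMM factors, chromosome 14 left out, the 6 libraries with raised atrial genes left out and the kidney covariate. For each difference given here the cause was not tested, except where fewer genes or libraries, or a stricter threshold, enter by construction.

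The counts for MstTg against wt (8385) and Mst1Gal3 against Gal3Ko (8013) stayed within 1.5 times their value in every alternative run except a required fold of 1.5, which left 3922 and 3612 by its construction. The genes called changed more than the counts under library totals. In order, 9955 and 9303 were called there, of which 6485 and 6041 were among the main calls. With each library left out in turn the counts of these comparisons ran from 8042 to 8456 and from 7573 to 8134. For Gal3Ko against wt (54) DESeq2 called 89, of which 53 were among the 54, a fit of these groups alone 33, the fit without the atrial libraries 33 (30 shared), the table without chromosome 14 14, a threshold of 0.01 30 and a fold of 1.5 27, and single libraries left out gave 38 to 80. For Mst1Gal3 against MstTg (746) a threshold of 0.01 left 356 and a fold of 1.5 260, and single libraries left out gave 469 to 1040. For the interaction (100) DESeq2 called 195, all 100 among them, a threshold of 0.01 left 15, and single libraries left out gave 52 to 189. The interaction was not run on the compared groups alone, since it needs all 4.

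The labels do not say that the replicate number pairs samples, and not every same-numbered pair deviated together: 12 of 34 pairs had a correlation over 0.1 (mean 0.0442, against -0.00714 over 217 other pairs), and 5 of 26 libraries correlated best with their own number. Between wt and Gal3Ko, however, 5 of 6 pairs were over 0.1 (0.224, 0.217, 0.247, 0.205 and 0.108, with -0.00599 for replicate 3), while MstTg and Mst1Gal3 pairs ran from -0.361 to 0.0323. A shared factor behind the wt and Gal3Ko numbers was not tested. With that number as a block the interaction count was 51 (16 higher and 35 lower), of which 40 were among the 100, and the other counts of genes were 8301, 42, 608 and 7911. The block ended 13 calls of named genes: Myh6 in MstTg against wt (adjusted p = 0.0524), Myh7 (0.06), Kcne1 (0.0823) and Rph3al (0.133) in Gal3Ko against wt, and Myh7 (0.0785), Scn4b (0.0523), Penk (0.0943), Ptk2b (0.0792), mt-Tq (0.0797), Oasl1 (0.0511), Loxl2 (0.154), Acaa2 (0.0578) and Mmp9 (0.122) in the interaction. It added that of Nppa in Mst1Gal3 against MstTg (0.0366).

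The slope of the Mst-1 responses (0.897) ran from 0.888 to 0.909 with single libraries left out. In those fits the same-sign share of the galectin-3 responses (70.2%) ran from 65.5 to 73.2%. That share was 60.6% under library totals and 68.2% with chromosome 14 left out. Camera with an estimated correlation called 7, 0, 6, 7 and 2 lists in MstTg against wt, Gal3Ko against wt, Mst1Gal3 against MstTg, Mst1Gal3 against Gal3Ko and the interaction, in place of 13, 12, 13, 12 and 16. Fry called 24, 0, 11, 19 and 5, and library totals gave 6 lists for Gal3Ko against wt. With single libraries left out the lists called ran from 13 to 15, 4 to 19, 11 to 16, 12 to 12 and 12 to 17.

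Among named genes, counted once per comparison, 1 reversed: Myh6 in MstTg against wt, 0.0404 (adjusted p = 0.686) under library totals. Values called under neither setting were counted as unchanged whatever their sign. RLE factors kept 232 named values and ended 2 calls, DESeq2 kept 228 and added 6, limma-voom kept 223, ended 10 and added 1, quality weights kept 216, ended 12 and added 6, and the block kept 220, ended 13 and added 1. Without the atrial libraries 220 were kept and 13 calls ended, and with the kidney covariate 229 were kept, 3 ended and 2 were added. Over all fits without 1 library 5963 values were kept, 107 calls ended and 14 were added. Spp1 passed in Mst1Gal3 against MstTg only with the kidney covariate (-0.66, adjusted p = 0.00556). For list values, RLE kept 154 and added 1, and fits without 1 library kept 3843, ended 119 and added 68.

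The planned Xist covariate was not run, because Xist is not in the table, and the alternative with no filter moved nothing, because the filter removed 0 genes. Genes under 10 counts on average are not in the deposited table, so nothing is known of them. Lgals3 was not called between Gal3Ko and wt in any alternative run. In data simulated at 1 common dispersion the interaction recovered 50% of 1.5-fold changes, so smaller interactions would mostly be missed in that setting. The differing spread of single genes and the broad Mst-1 response were not simulated.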

Other observations

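Several loci carried values that belong to no list. Ccnb1ip1, whose annotated transcription start lies within Rpph1 on the same strand, had 0 counts in all wt and MstTg libraries, 14 to 40 in Gal3Ko and 5 to 22 in Mst1Gal3. The copies Rprl2 and Rprl3 share 1.54% and 5% of their 260 words of 31 bases with Rpph1. Ogdhl, at 15.04 Mb from Lgals3, had 3363 to 5162 counts in wt and 166 to 433 in MstTg, against 26 to 1830 in Gal3Ko and 11 to 20 in Mst1Gal3, and within Gal3Ko replicates 2 (1450) and 3 (1830) stood highest. Ptprn2 ranged from 2 to 725 counts within wt and from 336 to 878 in Gal3Ko. These loci, apart from Rprl2, Rprl3, Ogdhl and Ptprn2, which the rule names, were singled out after their values were seen.

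The sum of the atrial genes Myl7, Myl4, Sln and Mybphl exceeded 30 CPM in 6 libraries: wt replicate 5 (34.7), MstTg replicate 5 (36.6), Gal3Ko replicates 4 (41.9), 5 (54.5) and 8 (131) and Mst1Gal3 replicate 3 (136). The other 20 libraries had 1.24 to 22.3 CPM.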
